A study of Solanum lycopersicum with 24 samples.

How the data were processed

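RNA of the glandular cells of type VI leaf trichomes was sequenced from the tomato af mutant and 2 complemented lines, CHI4 and CHI9, with 4 independent collections of each genotype. Per the labels' protocols, total RNA was extracted with an RNeasy kit and libraries were made with the TruSeq RNA Library Prep Kit. The deposited files hold counts per gene model, 1 file per sequencing lane, 24 files for 12 libraries. Per the labels, the authors used Trimmomatic, TopHat2, SAMtools and HTSeq, and no version, option or order is recorded. The genome build and annotation are not given in the sources used here, and neither is strand-specific counting, so reads of overlapping and antisense genes cannot be assigned. The values were checked to be whole numbers, with no normalization. Each table has 34725 gene models, of which 24536 had a read in some library, and 5 summary entries that name no gene and were left out of library sizes and tests. Against the gene counts plus these entries, reads in no gene took 8.49% to 12.2%, ambiguous reads 3.67% to 6.68% and reads with several alignments 4.68% to 7.56%. Of the counts from 1 to 10 in a lane file, 61.4% to 71.8% were even (median 68.6%), and whether a count stands for a read or for a read pair is not recorded, so a run with all counts halved and rounded was added as an alternative.

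The lanes of a library were treated as repeat runs and summed. A chi-square over genes divided by its degrees of freedom, which is 1 for sampling noise alone, compared the lanes of each library. It was 1.87 to 2.21 in 10 libraries, 8.15 in af replicate 4 and 5.69 in CHI4 replicate 4, against 34.2 to 146 between libraries of a genotype. Libraries held 20.9 to 70.9 M counts in af, 34.0 to 52.0 M in CHI4 and 8.99 to 46.1 M in CHI9. The floor given for a count of 0 is 3 counts over the library total, and covers counting error only.

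Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, which left 18326 genes, and libraries were scaled by TMM, with factors of 1.10 to 1.28 in af and 0.853 to 0.988 in the lines. A robust quasi-likelihood model with the 3 genotypes in 1 fit was tested for af against the mean of the lines, af against each line, and CHI9 against CHI4. Adjusted p-values are Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Printed CPM are TMM-scaled, and log2 differences are edgeR's fitted values with their standard errors (SE). Shared calls of both lines were set beside 20 simulations of unchanged lines and beside splits of the af libraries. Shares of all gene counts were compared by two-sided exact permutation tests.

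The collection numbers pair the samples because the labels mark a sampling time shared by the genotypes. Deviations from the genotype means correlated at -0.0394 to 0.184 between libraries of a collection (median 0.109, 7 of 12 pairs over 0.1), against a median of -0.0324 for other pairs, and 10 of 12 libraries correlated best with their own collection. The main fit has no block, so its p-values do not use this pairing. A fit with the collection as an additive block is an alternative.

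Gene lists, comparisons, tests and the rule for named genes were fixed before the data were examined. The rule takes CHI1, the 10 largest rises and falls of af against the lines among genes called the same way against both lines, with a mean of at least 5 CPM and no overlap of af with line libraries, members of the lists, and the 5 largest rises and falls between the lines. That CHI1 is the gene mutated in af comes from general knowledge and is not in the labels. The files do not pair locus numbers with names, and none of the 41476 genes of the reference table matched by identifier (0 matches). Names come from locus numbers written down beforehand from general knowledge, 107 loci in 14 of 25 lists, and could not be checked against an annotation. The other 11 lists were to be filled by description and are void, among them DNA damage and repair. A further 10 lists with 77 loci were added after the files were opened and before gene values were examined. At most 2 genes without a name that rose and 2 that fell are printed per comparison, besides genes printed for their place. Lists of at least 3 tested loci were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 13 fixed or the 9 added lists. Of the 8 fixed lists called, 4 were called with an estimated correlation (MEP, prenyl, terpene synthase and acylsugar lists), and of all 13 fixed lists tested 10 passed fry, which asks only whether a list's genes move, on balance, in a direction.

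The model was tested on simulated data with 200 changed genes among 18326. For af against the lines it recovered 8%, 46%, 86% and 98% of genes changed by 0.5, 1, 2 and 3 on the log2 scale with 6 false calls, and for CHI9 against CHI4 0%, 46%, 70% and 96% with 8. Of 20 simulated lists without a change, 0 were called. Simulated genes were drawn independently of each other, so this does not test lists of correlated genes. Far fewer genes were changed than were called in the data, so a large shift in composition was not tested either. The alternatives were RLE factors, DESeq2 1.42.0, limma-voom, no low-count filter, the collection block, only the genotypes compared, lane 1 or lane 2 alone, and each of 12 libraries left out. Lane 2 alone for the libraries with uneven lanes, upper-quartile scaling, halved counts and permutation of list shares within collections were added after seeing the data.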

Results

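Transcripts were counted in the glandular cells of type VI trichomes, the leaf hairs of tomato that store terpenes and flavonoids. The plants were the anthocyanin free (af) mutant and 2 complemented lines, CHI4 and CHI9. The labels name the genotypes only in these words, and that af lacks a working chalcone isomerase, which the lines have again, is general knowledge that was not checked here. Each of the 3 genotypes was collected 4 times, which gave 12 libraries, each sequenced on 2 lanes. The libraries held between 8.99 M counts (CHI9 replicate 2) and 70.9 M (af replicate 1), with a median of 39.4 M, and 17252 to 20997 genes had reads. A count of 0 in a library allows a level of up to 0.0423 counts per M (CPM) in the deepest library and 0.334 CPM in the shallowest, for counting error only, and 2-fold more if both mates of a read pair were counted, which is not recorded. The 100 most abundant genes took 34.0% ± 2.36 (SD, n = 4) of the counts in af, 45.2% ± 2.03 (SD, n = 4) in CHI4 and 42.1% ± 1.70 (SD, n = 4) in CHI9. On the first principal component of log CPM, which held 30.6% of the variance, the 4 af libraries lay apart from the 8 line libraries. CHI9 replicate 2, the shallowest library, lay apart too, at 104 on this component, with the other line libraries between 17.7 and 49.7, and at 120.1 on the second, with the other 11 libraries between -70.1 and 31.8. Positions are given as locus numbers, since the genome build is not given in the sources used here.

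Lanes of a library are repeat runs of it. In af replicate 4, lane 2 held 0.450 counts for each count of lane 1, against 0.985 to 0.988 in the other af libraries, and the ratio ran from 0.605 on chromosome 1 to 0.398 on chromosome 10. In CHI4 replicate 4 it ran from 1.13 on chromosome 1 to 0.965 on chromosome 10. The summed counts of these libraries therefore weight chromosomes unevenly. With lane 2 alone for both libraries, an alternative chosen after seeing the data, 4588 of the 4858 genes that differed between af and the lines were still called.

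**Figure D1:**
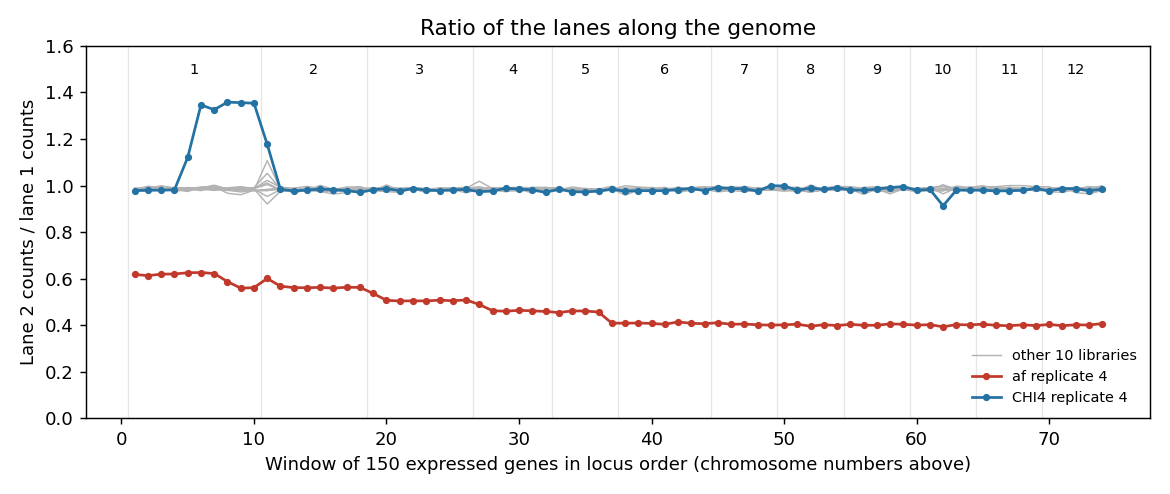
Ratio of lane 2 to lane 1 counts (y axis) in windows of 150 expressed genes in locus order (x axis), with 1 line per library. In af replicate 4 the ratio steps down from chromosome 1 (0.605 over the whole chromosome) to 0.398 on chromosome 10, in CHI4 replicate 4 it is raised over part of chromosome 1 and in the first window of chromosome 2 (1.18), and the other 10 libraries stay within 0.174 of their own median on the log2 scale.

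Chalcone isomerase (CHI1, Solyc05g010320), the enzyme that closes the flavanone ring early in flavonoid synthesis, is taken from general knowledge as the gene mutated in af and restored in the lines. Its transcript was present in af, at 260.5 ± 55.8 CPM (SD, n = 4), and higher in both lines, at 831 ± 331 CPM (SD, n = 4) in CHI4 and 685 ± 110.4 CPM (SD, n = 4) in CHI9. The log2 difference between af and the mean of the lines was -1.53 (SE 0.229, edgeR adjusted p = 7.76e-05). The highest af library held 339.9 CPM (af replicate 3) and the lowest line library 418 CPM (CHI4 replicate 1), so on that reading no library went against its label. Counts of the native gene and of the introduced copy cannot be separated in these tables.

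The first comparison asked what differs between mutant and complemented gland cells. Genes of terpenoid synthesis were lower in af, while the chalcone synthases CHS1 and CHS2 and flavanone 3-hydroxylase (F3H), abundant enzymes of the flavonoid pathway, did not pass the threshold. Neryl diphosphate synthase (NDPS1, Solyc08g005680), which makes the precursor of the monoterpenes of this trichome, had 768 ± 159 CPM (SD, n = 4) in af, 7959.8 ± 1039 CPM (SD, n = 4) in CHI4 and 7519.8 ± 664 CPM (SD, n = 4) in CHI9. The terpene synthase TPS12 (Solyc06g059930) had 2621 ± 329 CPM (SD, n = 4) in af, 9717 ± 1555 CPM (SD, n = 4) in CHI4 and 9777 ± 922 CPM (SD, n = 4) in CHI9. In contrast, the trichome regulator EOT1 (Solyc02g062400) was higher in af, at 204 ± 25.5 CPM (SD, n = 4) against 98.2 ± 15.1 CPM (SD, n = 4) in CHI4 and 107 ± 14.8 CPM (SD, n = 4) in CHI9.

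**Figure D2:**
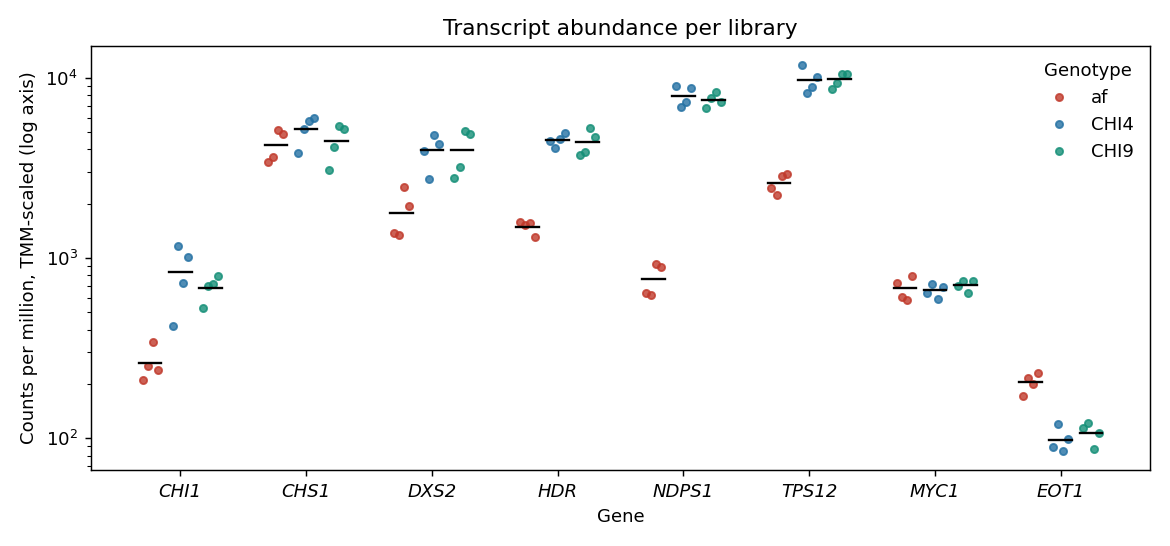
TMM-scaled counts per M (y axis, log scale) of 8 genes (x axis), with 1 point per library (4 per genotype) and a bar at the mean of each genotype. NDPS1 has a mean of 768 in af against 7959.8 in CHI4 and 7519.8 in CHI9, while MYC1 has means of 677, 661 and 707.

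Of the 8 tested loci of the methylerythritol phosphate (MEP) pathway, which supplies isoprenoid precursors in plastids, 7 fell in af over all genes tested (8 adjusted over the list alone). HDR (Solyc01g109300), the last enzyme of the pathway, fell by 1.58 on the log2 scale (SE 0.150, adjusted p = 3.39e-07), and DXR (Solyc03g114340) fell by 1.58 (SE 0.211, adjusted p = 1.56e-05). DXS2 (Solyc11g010850), which feeds the pathway in trichomes, fell by 1.15. CMK (Solyc01g009010) had a log2 difference of -1.48, MDS (Solyc08g081570) -1.38, HDS (Solyc11g069380) -1.20 and MCT (Solyc01g102820) -0.80, all past the threshold, and DXS1 (Solyc01g067890) had -0.29 with an adjusted p of 0.0907. The list as a whole was lower in af (camera adjusted p = 1.24e-10, and adjusted p = 0.0224 with an estimated correlation). The 4 tested loci of HMG-CoA reductase, an enzyme of the cytosolic mevalonate pathway, had log2 differences from -0.44 to 0.57, with 0.06 for HMGR2 (Solyc02g038740). Of these, 0 passed the edgeR test, also 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. With the collection as a block 1 was higher and 1 lower in af. The list had a camera adjusted p of 0.981.

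Of 6 tested loci of prenyl diphosphate synthases and isomerase, which build the terpene precursors, 4 fell (5 adjusted over the list alone, and 5 with the collection as a block). NDPS1 fell by 3.33 (SE 0.183, adjusted p = 2.78e-10), GGPPS2 (Solyc04g079960) fell by 1.95, GGPPS3 (Solyc02g085700) fell by 1.35 and IDI (Solyc04g056390) fell by 1.17. Of 11 tested terpene synthases 10 fell (11 adjusted over the list alone, and 11 with the collection as a block). TPS33 (Solyc01g101170) fell by 3.84, TPS17 (Solyc12g006570) fell by 3.71, the TPS19/20 locus Solyc08g005670 fell by 2.79 and TPS12 fell by 1.90 (SE 0.161, adjusted p = 8.09e-08). TPS39 (Solyc10g005390), TPS18 (Solyc08g005640), TPS21 (Solyc08g005720), TPS5 (Solyc01g105890) and TPS38 (Solyc10g005410) had log2 differences of -3.16, -2.41, -2.05, -1.45 and -1.37, each past the threshold. TPS3 (Solyc01g105870) had 0 counts in af and was scarce in the lines, at 0.292 CPM in CHI4 and 0.409 in CHI9 (adjusted p = 0.0205, which was 0.0778 with limma-voom, 0.0570 without af replicate 1 and 0.0568 without af replicate 2). TPS8 (Solyc01g105850) had a log2 difference of -0.64 and an adjusted p of 0.0850. This was 0.0209 with DESeq2, 0.0377 with limma-voom, 0.000175 with the collection as a block, 0.0174 without af replicate 3 and 0.0477 without CHI4 replicate 2. Prenyl and terpene synthase lists were both lower in af (camera adjusted p = 1.36e-11 and 6.92e-21, and adjusted p = 0.00378 for each with an estimated correlation). TPS19 and TPS20 are near-identical copies between which the counting could split reads, so that value is uncertain.

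As a share of all gene counts without any scaling, MEP loci took 0.718% ± 0.0289 (SD, n = 4) in af and 1.34% ± 0.176 (SD, n = 8) in the lines. Terpene synthases took 0.454% ± 0.0433 (SD, n = 4) in af and 1.42% ± 0.138 (SD, n = 8) in the lines, and the prenyl list took 0.404% ± 0.0461 (SD, n = 4) and 1.22% ± 0.0656 (SD, n = 8). Each of these shares differed by a two-sided exact permutation test (p = 0.00202, the smallest that 495 arrangements allow, and 0.00269 adjusted over 4 lists). With arrangements only within collections, a test added after these shares were seen, p was 0.0123 for each, the smallest that 81 arrangements allow.

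Of 12 tested flavonoid loci 4 fell in af (over all genes), and 4 were lower and 1 higher adjusted over the list alone (with the collection as a block 5 were lower and 2 higher over all genes). Log2 differences in the list ran from -2.45 to 2.31, with 0 loci called higher over all genes in the main fit. The 4 that fell were CHI1 itself, flavonoid 3'5'-hydroxylase (Solyc11g066580), a flavonoid 3-O-glucosyltransferase (Solyc10g083440) and an anthocyanin rhamnosyltransferase (Solyc09g059170). The rhamnosyltransferase fell by 0.74 (SE 0.146, adjusted p = 0.000805) and the glucosyltransferase fell by 0.65. The hydroxylase was scarce, at 0.624 CPM in af, 2.17 in CHI4 and 5.62 in CHI9. Chalcone synthases CHS1 (Solyc09g091510) and CHS2 (Solyc05g053550), which make the substrate of CHI1, had log2 differences of -0.17 (SE 0.181) and -0.13 (SE 0.172), F3H (Solyc02g083860) 0.12 (SE 0.170) and flavonol synthase (FLS, Solyc11g013110) -0.03 (SE 0.223). The chalcone isomerase-like gene CHIL (Solyc05g052240) had -0.65 and an adjusted p of 0.175, which was 0.000226 with the collection as a block and 0.0161 without af replicate 3. Flavonoid 3'-hydroxylase (Solyc03g115220) had 0.32 and an adjusted p of 0.331, which was 0.0220 with that block. The list did not pass the camera test, whose direction in the main fit was lower in af (adjusted p = 0.139, and 0.0479 without CHI4 replicate 1). Its share of all gene counts was 2.15% ± 0.278 (SD, n = 4) in af and 1.87% ± 0.336 (SD, n = 8) in the lines (two-sided exact permutation p = 0.188). Within collections it was higher in af than in the mean of the lines in 4 of 4 (exact permutation p = 0.0247 over 81 arrangements within collections, also 0.0247 adjusted over 4 lists). The share, which is unscaled and weighted by the abundant loci, thus went the opposite way to the camera test. The direction of the list depends on the measure. The topics of the flavonoid, MEP, prenyl, terpene synthase and reactive oxygen lists were chosen knowing what the study is about, so their counts and directions are not independent evidence.

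**Figure D3:**
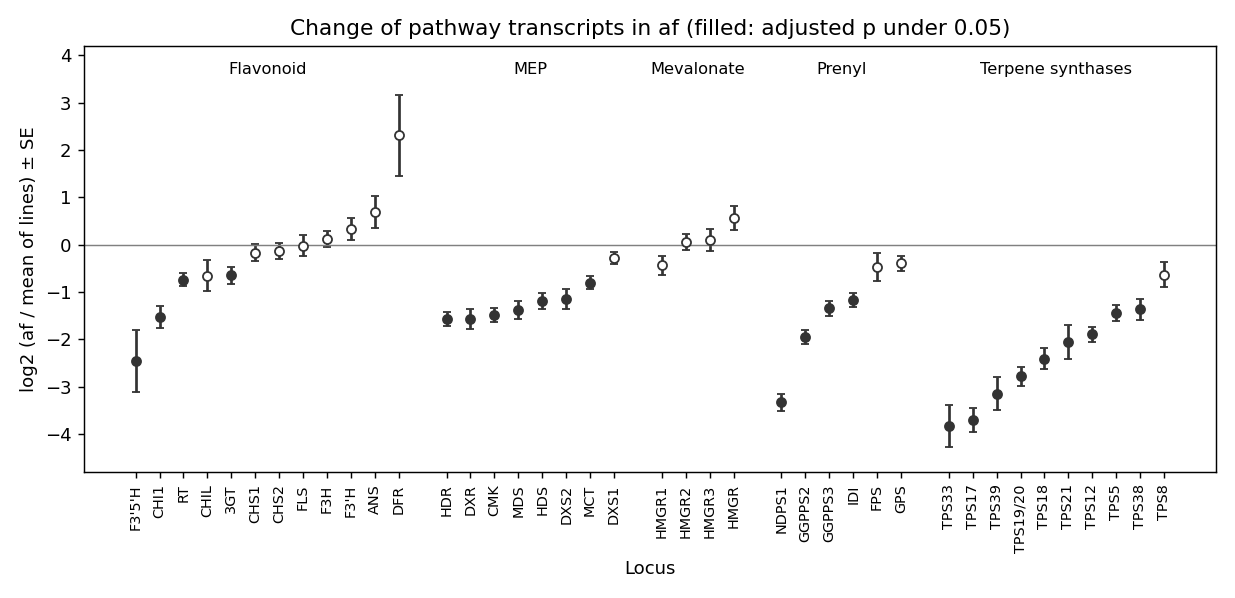
Log2 ratio of af to the mean of the lines with its standard error (y axis) for loci of 5 lists that reached 1 CPM (x axis), filled where the edgeR adjusted p was under 0.05. MEP, prenyl and terpene synthase loci lie below 0, with filled points from -0.80 (MCT) to -3.84 (TPS33), and CHS1, CHS2 and FLS lie near 0.

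Of 8 tested loci of phenylpropanoid entry, which leads to the flavonoid pathway, 1 rose and 2 fell, and adjusted over the list alone the counts were 1 and 2 (with the collection as a block 3 and 2 over all genes). The phenylalanine ammonia-lyase (PAL) Solyc09g007900 rose by 0.55 (adjusted p = 0.0637 without af replicate 4), and the PAL Solyc10g086180 fell by 1.34 (adjusted p = 0.0508 without af replicate 2). Cinnamate 4-hydroxylase (C4H, Solyc05g047530) had 0 counts in af, 0.576 CPM in CHI4 and 0.192 CPM in CHI9. The list's median log2 difference was 0.42 and its mean, which rests on the fitted value of C4H, -0.93, with a camera adjusted p of 0.981 in the direction of the mean. Of 4 tested trichome regulators 2 rose (also 2 adjusted over the list alone), EOT1 by 0.99 (SE 0.128, adjusted p = 1.04e-05) and Woolly (Solyc02g080260), a regulator of trichome formation, by 1.76 at 2.38 CPM in af. The adjusted p of Woolly was 0.0866 without af replicate 1 and 0.0572 without af replicate 4, and 0.0711 with lane 1 alone. MYC1 (Solyc08g005050), a regulator of type VI trichomes and their terpenes, had 677 ± 98.5 CPM (SD, n = 4) in af, 661 ± 57.7 CPM (SD, n = 4) in CHI4 and 707 ± 49.98 CPM (SD, n = 4) in CHI9. The regulator list had a camera adjusted p of 0.0766 (0.0463 without CHI4 replicate 2 and 0.0487 without the low-count filter).

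Of 4 tested acylsugar loci, markers of the tip cells of other trichome types, 2 fell (3 adjusted over the list alone). The acyltransferase ASAT3 (Solyc11g067270) fell by 1.99 (SE 0.212, adjusted p = 1.24e-06), and IPMS3 (Solyc08g014230) fell by 0.60, with an adjusted p of 0.0536 without af replicate 2. The list was lower in af (camera adjusted p = 0.00193, and adjusted p = 0.0224 with an estimated correlation). Of 3 tested genes of the Rubisco small subunit, taken beforehand as markers of green leaf cells, 1 fell (2 adjusted over the list alone), Solyc02g063150 by 1.86 (SE 0.144, adjusted p = 2.66e-08). Whether gland cells express these genes too was not checked. The more abundant Solyc03g034220 had 228 ± 31.7 CPM (SD, n = 4) in af, 261 ± 21.9 CPM (SD, n = 4) in CHI4 and 264 ± 18.3 CPM (SD, n = 4) in CHI9. That list had a camera adjusted p of 0.00277, and adjusted p = 0.101 with an estimated correlation.

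Of 7 tested enzymes that remove reactive oxygen 3 fell (4 adjusted over the list alone, and with the collection as a block 4 fell and 1 rose). The catalase CAT2 (Solyc02g082760) fell by 0.78, CAT3 (Solyc04g082460) fell by 0.77 and the superoxide dismutase Solyc11g066390 fell by 0.86. The superoxide dismutase Solyc01g067740 had a log2 difference of -0.03 and the ascorbate peroxidase APX1 (Solyc06g005160) -0.33. The list had a camera adjusted p of 0.0150, which was 0.0502 without af replicate 3, and adjusted p = 0.192 with an estimated correlation. Of 5 tested proteinase inhibitors and polyphenol oxidases 1 fell (2 adjusted over the list alone, and 2 with the collection as a block), the polyphenol oxidase Solyc08g074620, which had 2129 ± 313 CPM (SD, n = 4) in af, 6096 ± 228 CPM (SD, n = 4) in CHI4 and 6607 ± 880.0 CPM (SD, n = 4) in CHI9. Camera gave this list an adjusted p of 0.0198, and adjusted p = 0.0874 with an estimated correlation. Of 6 tested jasmonate loci 2 fell (also 2 adjusted over the list alone), and they were AOS2 (Solyc11g069800, which fell by 1.64) and AOC (Solyc02g085730, which fell by 1.02), enzymes of jasmonate synthesis. The jasmonate list had a camera adjusted p of 0.0453, and adjusted p = 0.104 with an estimated correlation. Its adjusted p was 0.0709 with the collection as a block, 0.0842 without af replicate 3 and 0.0749 without CHI9 replicate 4. With lane 2 alone for all libraries it was 0.0711, with lane 2 alone for the libraries with uneven lanes 0.0509, and with halved counts 0.0552.

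Of 3 tested class I small heat shock proteins 1 rose (also 1 adjusted over the list alone, and 3 with the collection as a block), Solyc06g076570 by 1.26 (adjusted p = 0.0467). The call was lost when any of af replicate 1, af replicate 2, af replicate 4, CHI4 replicate 1, CHI4 replicate 3, CHI4 replicate 4, CHI9 replicate 2, CHI9 replicate 3 or CHI9 replicate 4 was left out (adjusted p from 0.0655 to 0.136), and its adjusted p was 0.0855 without the low-count filter, 0.0509 with lane 1 alone and 0.0540 with lane 2 alone for the libraries with uneven lanes. The list had a camera adjusted p of 0.140, which was 0.0226 without CHI4 replicate 2. The dehydrin TAS14 (Solyc02g084850), the 1 tested locus of its list, had a log2 difference of -0.69 and an edgeR adjusted p of 0.619, so 0 loci of this list passed in edgeR, 0 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom.

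Over all 18326 tested genes, 2358 were higher and 2500 lower in af than in the mean of the lines (edgeR quasi-likelihood, adjusted p under 0.05). Of these, 1115 were higher and 961 lower by at least 2-fold. With the collection as a block 2889 genes were higher and 2919 lower, and 4791 of the 4858 calls without a block were kept. Among genes with a mean of at least 5 CPM, no overlap of af with line libraries and calls against both lines, a rule fixed before the data were examined, most of the largest changes were in genes without a name in the sources used here. Among the 10 largest rises by this rule 10 had no name, and among the 10 largest falls 9 had none, TPS33 being the exception. Only 135 of the 18326 tested genes had a name, so genes without one would fill most places of any ranking. Solyc02g094270 had 6.54 CPM in af, with 6 counts over the 4 CHI4 libraries and 0 over the 4 CHI9 libraries. Solyc03g116820 had 13.6 CPM in af, with 5 counts in CHI4 and 8 in CHI9. The largest falls by this rule were Solyc12g096240, at 0.159 CPM in af, 19.7 in CHI4 and 9.90 in CHI9, and Solyc07g054780, at 0.333, 28.2 and 21.4 CPM.

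Each line was then compared with af on its own. NDPS1 fell by 3.37 against CHI4 (adjusted p = 1.04e-09) and by 3.29 against CHI9 (adjusted p = 1.46e-09). DXR fell by 1.58 and 1.57, TPS12 fell by 1.89 and 1.90, and EOT1 rose by 1.05 and 0.93. IPMS3 passed against CHI4 (adjusted p = 0.000777) and had an adjusted p of 0.399 against CHI9, and its difference between the lines did not pass (adjusted p = 0.282). Against CHI4, 1588 genes were higher and 2049 lower in af, and against CHI9 1623 were higher and 2127 lower. In both comparisons 1032 genes were higher and 1668 lower, 2700 in all (1456, 2055 and 3511 with the collection as a block). Independent lists of the sizes without a block would share 141 higher and 238 lower genes, and 20 simulations of unchanged lines against the same af libraries gave at most 0 shared genes. These simulations called 0 genes against either line, so they give no measure of the sharing that comes from the common af libraries. With the af libraries split into pairs, each pair used for 1 line, the 6 possible assignments gave 1316 to 1402 shared genes, against 130.1 to 157 for independent lists.

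The last comparison asked whether the complemented lines differ from each other. CHI9 was higher than CHI4 at 11 genes and lower at 6. Of the 11, 3 lie close together on chromosome 2, and the outermost of them are named here because of their place, which was seen after their values. Solyc02g070590 had 387 ± 55.9 CPM (SD, n = 4) in CHI9 and 97.7 ± 16.8 CPM (SD, n = 4) in CHI4, with an adjusted p of 0.0476. Solyc02g070670 had 115 ± 13.7 CPM (SD, n = 4) in CHI9 and 57.6 ± 6.83 CPM (SD, n = 4) in CHI4, with an adjusted p of 0.00717 (0.0507 without CHI4 replicate 1). The call of Solyc02g070590 was lost when any of af replicate 3, CHI4 replicate 1, CHI4 replicate 2, CHI4 replicate 3, CHI4 replicate 4, CHI9 replicate 1, CHI9 replicate 2, CHI9 replicate 3 or CHI9 replicate 4 was left out (adjusted p from 0.0840 to 0.210), and its adjusted p was 0.162 without the low-count filter, 0.0529 with lane 1 alone and 0.0533 with upper-quartile scaling. Among genes of at least 5 CPM the largest excess of CHI9 over CHI4 was that of Solyc02g062730. It had 4 counts over the CHI4 libraries and 512 over the CHI9 libraries (adjusted p = 0.000676, and 0.000119 with the collection as a block). Its mean was 5.88 ± 4.92 CPM (SD, n = 4) in CHI9 and 3.91 CPM in af. Against af it passed in CHI4 (adjusted p = 2.39e-05) and not in CHI9 (0.586), so CHI4 was the line that departed from af. The smallest adjusted p was that of Solyc07g007040, at 47.6 CPM in CHI9 and 12.7 in CHI4 (5.76e-06, and 5.13e-07 with the collection as a block). It had 98.1 CPM in af and was lower than that in both lines. Solyc05g013150 fell by 2.84 in CHI9 (adjusted p = 0.0111, and 0.0635 without CHI9 replicate 3, 0.0793 with limma-voom and 0.0502 with only the genotypes compared), and Solyc06g073500 fell by 2.24 (adjusted p = 0.00437, and 0.325 with limma-voom).

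**Figure D4:**
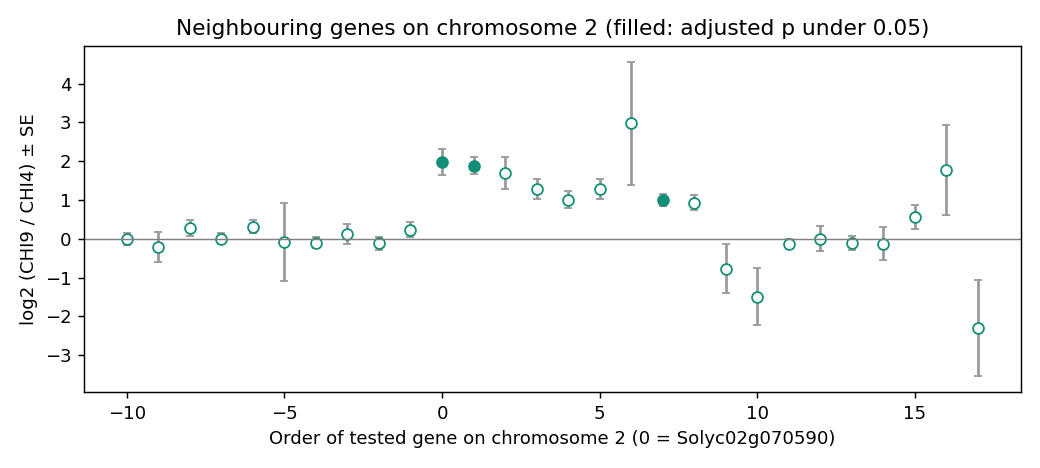
Log2 ratio of CHI9 to CHI4 with its standard error (y axis) for tested genes in locus order (x axis) around the neighbouring called genes on chromosome 2. The 8 tested genes of the segment lie between 1.00 and 2.98, with a median of 1.49, and the 20 flanking genes have a median of -0.04. The flanking gene next to the right end has 0.93 (SE 0.189, adjusted p = 0.0746).

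Of the 135 tested loci of all lists, 0 differed between the lines in edgeR, with 16 at an unadjusted p under 0.05, 1 with the collection as a block, 3 called by DESeq2 and 0 by limma-voom. The count of 17 genes was 36 with the collection as a block, 92 with DESeq2 and 10 with limma-voom. It was 9 without CHI4 replicate 1, 10 without CHI4 replicate 3, CHI9 replicate 3 or CHI9 replicate 4, and 11 without CHI9 replicate 1.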

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

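The tests of lane losses, of gland share, of scaling and of random position were chosen only after the results were seen, and those of other splits before. The prediction for the rest of the chromosome 2 segment was written before that test, but the segment itself was picked from the called genes. The lane 2 counts of af replicate 4 were 0.450 of those of lane 1 (other af libraries 0.985 to 0.988), and its lanes differed by a chi-square of 8.15 per degree of freedom (others 1.95 to 2.03), as did those of CHI4 replicate 4 by 5.69 (others 2.03 to 2.07). Reads of a line in a lane of af replicate 4, or of af in a lane of CHI4 replicate 4, are argued against. The lane ratio hardly followed the difference between the lines and af across genes (r = -0.0491 over 10503 genes for af replicate 4 and -0.0203 over 11387 for CHI4 replicate 4, with genes not being independent replicates). Reads of CHI9 in CHI4 replicate 4 could not be seen in this way, since the lines differed at only 17 genes. For the steps of the ratio along the chromosomes a candidate explanation is reads lost by genome position in the lane 1 files, whose window medians spread 7.11 times as widely as those of lane 2 in af replicate 4 (SD 0.232 against 0.0326) and 3.45 times in CHI4 replicate 4 (SD 0.130 against 0.0376), but lost lane 1 reads would raise the ratio, so they leave the low lane 2 total of af replicate 4 unexplained. No biological explanation was tested, since lanes are runs of the same library.

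MEP pathway and terpene synthase transcripts were lower in af. A smaller share of gland cells in the af collections would lower other gland transcripts alike. The 7 flavonoid enzymes above 1000 CPM in the lines had a median log2 difference of -0.13 (from -0.74 for the rhamnosyltransferase, itself called lower, to 0.32, with -0.65 for CHIL), where MEP loci had a median of -1.29. These enzymes belong to the pathway of the gene taken as mutated in af, and the flavonol activator MYB12 was higher in af. They may therefore not gauge the gland share, which stays open as a cause. Scaling is argued against as the whole cause by the unscaled share of MEP counts, in which the lowest line library lay 0.377 percentage points above the highest af library. TMM factors were higher in af (1.10 to 1.28) than in the lines (0.853 to 0.988), which makes fitted falls larger than those in unscaled shares. The size of the falls therefore depends on the scaling. The acylsugar list, which marks other trichome types, was lower in af too (camera adjusted p = 0.00193), as were the lists taken as green leaf cell markers, of light-harvesting proteins (adjusted p = 0.000124, and 0.153 with an estimated correlation) and of the Rubisco small subunit (0.00277, and 0.101), so a change in the other cells collected stays open. Whether gland cells express these genes too was not checked. Lower transcription of terpenoid genes within gland cells, and its dependence on chalcone isomerase, stay open and were not tested.

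The lines differed at 17 genes by the test of the difference between their contrasts with af, 8 of which passed against af in CHI9 alone and 5 in CHI4 alone, and 3 of them lie together on chromosome 2. Random positions of the called genes are argued against by the 5 other tested genes of the segment, whose median log2 difference of 1.29 was reached by 7 of 18262 overlapping runs of as many neighbouring genes elsewhere (0.0383%), whereas a permutation p of 0.00420 for 3 called pairs within 20 tested genes (10000 placements) only restates what prompted the test. For reads lost from the CHI4 replicate 4 lane 1 file, the median log2 difference of these neighbours was 1.90 with lane 2 alone for the libraries with uneven lanes and 1.89 without that change. This run could hardly have given another outcome. It changed 1 of the CHI4 libraries, and the raised lane ratio on chromosome 2 was in its first window, which ends before the segment. A local effect on the whole segment may account for the pattern, since 100% of its 5 other genes had positive log2 estimates (1.01 to 2.98), but 0 of them passed in edgeR (4 at an unadjusted p under 0.05, 3 with the collection as a block, 4 in DESeq2 and 0 in limma-voom), and the next gene outside had 0.93 (adjusted p = 0.0746), so its extent is not settled. Whether such an effect comes from the place of the introduced copy, from an extra copy of the segment or from another difference between the lines was not tested.

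Other splits of the same libraries into groups of the same sizes were counted, the real split included. For af against the lines 1 of 60 splits drawn gave as many genes as the real 4858 (highest other 1). For af against CHI4 it was 1 of 35 (3637 genes, highest other 2), for af against CHI9 1 of 35 (3750 genes, highest other 49) and for CHI9 against CHI4 1 of 35 (17 genes, highest other 12). The splits that part the collections as the real one does, 11 of those drawn for af against the lines and 8 for each of the others, are too few for a share under 0.05, and the highest other among them gave 0 genes. The other splits, which put the libraries of some collections together, gave at most 1, 2, 49 and 12 genes in that order. Splits other than the real one mix genotypes within a group, so real differences add to the spread within groups and lower the calls. They therefore do not measure how many calls unchanged genotypes would give.

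A single library lay far from the other 3 of its genotype in 20 of 267 groups of 4. Chance gives about 1 in 20 such groups, or 13.3 here. Besides the lane values above, the lane 2 counts of CHI9 replicate 3 were 0.988 of those of lane 1 (other CHI9 libraries 0.982 to 0.983). DXR (Solyc03g114340) had 990.1 CPM in CHI4 replicate 2, with the other CHI4 libraries between 1855 and 1944. In CHI9 replicate 3, TPS8 (Solyc01g105850) had 302 CPM, and the others of that genotype lay between 158 and 164. For AOC (Solyc02g085730), CHI4 replicate 2 held 42.2 CPM beside 53.2 to 55.3 in the rest of CHI4. RbcS (Solyc03g034220) had 294 CPM in CHI4 replicate 4, with the other CHI4 libraries between 248 and 252. In CHI9 replicate 1, RbcS (Solyc03g034220) had 291 CPM, and the others of that genotype lay between 252 and 258. For HY5 (Solyc08g061130), CHI9 replicate 2 held 24.7 CPM beside 16.7 to 18.0 in the rest of CHI9. CAB (Solyc03g005760) had 321 CPM in CHI9 replicate 2, with the other CHI9 libraries between 271 and 278. In CHI4 replicate 2, CER6 (Solyc02g085870) had 66.6 CPM, and the others of that genotype lay between 40.5 and 42.2. For TAS14 (Solyc02g084850), af replicate 1 held 3.28 CPM beside at most 0.571 in the rest of af. AACS1 (Solyc07g043630) had 4.44 CPM in CHI4 replicate 2, with the other CHI4 libraries between 1.601 and 1.98. In af replicate 2, CAB (Solyc03g005780) had 5.46 CPM, and the others of that genotype lay between 2.01 and 2.59. For CD2 (Solyc01g091630), CHI9 replicate 1 held 44.8 CPM beside 32.3 to 33.6 in the rest of CHI9. Solyc03g116820 had 0.213 CPM in CHI9 replicate 3, with the other CHI9 libraries between 0 and 0.0260. In CHI4 replicate 1, Solyc02g070590 had 123 CPM, and the others of that genotype lay between 87.2 and 91.9. For Solyc06g073500, CHI4 replicate 3 held 4.17 CPM beside 9.40 to 10.5 in the rest of CHI4. Solyc06g073500 had 2.55 CPM in CHI9 replicate 4, with the other CHI9 libraries between 1.44 and 1.61.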

How the results depend on the processing

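Lane 2 alone for the libraries with uneven lanes, upper-quartile scaling and halved counts were chosen only after the data were seen. CHI1 stayed lower in af and past the threshold in each alternative run (log2 -1.69 to -1.43). Counts in af against the lines ranged from 1645 to 3270 (higher) and 1948 to 2966 (lower), against CHI4 from 2724 to 4628, against CHI9 from 2733 to 4737 and in both lines from 1982 to 3511, all within 1.5 times the main counts. More genes were higher than lower in af with limma-voom (3270 and 2706), upper-quartile scaling (2620 and 2306) and without CHI9 replicate 1 (2713 and 2648), and fewer with the main settings and in the other alternatives run. For CHI9 against CHI4 the 17 genes were 92 with DESeq2, 10 with limma-voom and 36 with the collection block, and 9 to 16 with a library left out, and the cause was not tested. Gene list calls went from 8 to 4 with an estimated correlation, and to 6 to 10 with a library left out. Among named genes and list tests the block changed the calls of TPS8, CHIL, flavonoid 3'-hydroxylase and the jasmonate list. Of all 135 tested listed loci, 15 gained a call with it and 0 lost one, and of the 17 calls between the lines 2 were lost. Of 80 pairs of a gene and a contrast chosen for these runs, other than CHI1, 66 were called, 49 of them in every alternative run, 17 lost the call in some, and 0 reversed. Those that lost it were TPS3, AACS1, Solyc05g013150, Solyc06g073500, HSP90, class I sHSP Solyc06g076570, AECH1, Solyc02g070590, Woolly, CD2, HY5, CCD1A, PAL Solyc10g086180, IPMS3, HSP101, PAL Solyc09g007900 and Solyc02g070670. Fitting only the genotypes compared does not apply to af against the lines, which uses all of them. Depth limits CHI9 replicate 2 most, where a count of 0 allows 0.334 CPM.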

Other observations

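The 10 lists described here were chosen after the files were opened and before gene values were examined, and the test of neighbouring calls after the main results were seen. Of 5 tested loci of steroidal glycoalkaloid synthesis 3 fell in af (also 3 adjusted over the list alone), GAME12 (Solyc12g006470) by 1.72 (SE 0.146, edgeR adjusted p = 7.93e-08), GAME17 (Solyc07g043480) with a log2 difference of -2.73 and GAME11 (Solyc07g043420) with -1.48. The list was lower in af (camera adjusted p = 0.000124, and adjusted p = 0.0185 with an estimated correlation). Of 8 tested light-harvesting proteins, taken as markers of green leaf cells, 4 fell (5 adjusted over the list alone), among them the CAB loci Solyc03g005760, at 88.6 ± 31.9 CPM (SD, n = 4) in af, 263 ± 36.5 CPM (SD, n = 4) in CHI4 and 285 ± 23.9 CPM (SD, n = 4) in CHI9, and Solyc03g005780, at 3.15, 27.0 and 19.9 CPM. That list had a camera adjusted p of 0.000124, and adjusted p = 0.153 with an estimated correlation. Of 12 tested carotenoid loci 2 rose and 5 fell (3 and 5 adjusted over the list alone). The desaturases PDS (Solyc03g123760) and ZDS (Solyc01g097810) had log2 differences of -0.87 and -1.18, the dioxygenase CCD1B (Solyc01g087260) -0.67 and its relative CCD1A (Solyc01g087250) 0.73, each past the threshold. Zeaxanthin epoxidase (ZEP, Solyc02g090890) rose by 2.64, from 1.45 CPM in CHI4 and 1.87 in CHI9 to 10.2 in af. The carotenoid list had a median log2 difference of -0.38 and a mean of 0.17, so the signs differ, and a camera adjusted p of 0.308 in the direction of the median. Both further acylsugar loci, AACS1 (Solyc07g043630) and AECH1 (Solyc07g043680), were lower in af, with log2 differences of -2.75 and -2.49 (adjusted p = 0.00645 and 0.0399). The adjusted p of AACS1 was 0.0634 with limma-voom, and that of AECH1 0.0694 without the low-count filter. AECH1 lost its call when any of af replicate 2, af replicate 4, CHI4 replicate 1, CHI4 replicate 2, CHI4 replicate 3, CHI4 replicate 4, CHI9 replicate 1, CHI9 replicate 2 or CHI9 replicate 3 was left out (adjusted p from 0.0516 to 0.114), and CCD1A when af replicate 1 or af replicate 3 was (adjusted p from 0.0511 to 0.0540).

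Of 5 tested flavonoid regulators 2 rose (3 adjusted over the list alone). MYB12 (Solyc01g079620), an activator of flavonol synthesis, had 169 ± 26.6 CPM (SD, n = 4) in af, 95.4 ± 36.7 CPM (SD, n = 4) in CHI4 and 73.9 ± 13.4 CPM (SD, n = 4) in CHI9, and the light-signalling factor HY5 (Solyc08g061130) rose by 0.90 (adjusted p = 0.0206, and 0.0561 to 0.118 without af replicate 1 or af replicate 4). The list had a camera adjusted p of 0.232. Of 6 tested heat shock loci 2 rose (also 2 adjusted over the list alone), the chaperones HSP101 (Solyc03g115230) by 2.09 and HSP90 (Solyc06g036290) by 2.19, with wide spreads in af of 84.1 ± 61.4 CPM (SD, n = 4) and 164 ± 105 CPM (SD, n = 4). HSP101 lost its call when either af replicate 2 or af replicate 4 was left out (adjusted p from 0.0783 to 0.0907), and HSP90 when any of af replicate 1, af replicate 2, af replicate 4, CHI4 replicate 1, CHI4 replicate 2, CHI4 replicate 3, CHI9 replicate 1, CHI9 replicate 2, CHI9 replicate 3 or CHI9 replicate 4 was left out (adjusted p from 0.0511 to 0.136), and the adjusted p of HSP90 was 0.0622 without the low-count filter, 0.0519 with lane 1 alone and 0.0504 with lane 2 alone for the libraries with uneven lanes. The camera adjusted p of that list was 0.250. Of 3 tested cuticle loci 2 rose (3 adjusted over the list alone), the wax enzyme CER6 (Solyc02g085870) by 0.89 and the cutin regulator CD2 (Solyc01g091630) by 0.43, with a camera adjusted p of 0.0775. CD2 lost its call when any of af replicate 1, af replicate 2, af replicate 3, CHI4 replicate 1, CHI4 replicate 3, CHI4 replicate 4, CHI9 replicate 2, CHI9 replicate 3 or CHI9 replicate 4 was left out (adjusted p from 0.0555 to 0.148), and its adjusted p was 0.0790 with lane 1 alone. Of 5 drought loci 1 fell (also 1 adjusted over the list alone, and 2 with the collection as a block), ASR1 (Solyc04g071610) by 1.29, and camera gave an adjusted p of 0.0784. Pathogenesis-related and ethylene lists each had 0 of 4 tested loci called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, with camera adjusted p = 0.695 for each.

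Genes called in the same direction lay next to each other more often than in 1000 shuffles of the calls along the tested genes. Adjacent pairs numbered 389 among genes higher in af, against 303 ± 15.4 (SD over shuffles, maximum 355), and 492 among genes lower in af, against 339.8 ± 15.7 (maximum 398). These calls came from the summed counts, in which the libraries with uneven lanes weight chromosomes unevenly. The shuffles did not account for this. They also moved genes singly, so that close loci of a gene family were not kept together. Such loci are among the calls lower in af, as with the terpene synthases Solyc08g005640, Solyc08g005670 and Solyc08g005720. Whether the excess remains without the uneven lanes or without such families was not tested.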
